A study of Mus musculus with 12 samples.

How the data were processed

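RNA was measured on single-colour whole-transcript microarrays in cells of a mouse T cell acute lymphoblastic leukaemia (T-ALL) clone, number 483, of C57BL6 background. Per the labels, the cells received 4EGI-1, a small molecule that blocks the binding of the cap-binding protein eIF4E to the scaffold protein eIF4G, at 100 µM for 2 h, or no inhibitor. The labels call the control cells untreated, while the protocol text names DMSO, the solvent, as the control. Cytoplasmic RNA and RNA from pooled polysome fractions of a sucrose gradient were profiled, which gives 4 groups of 3 arrays and 12 arrays in all. The labels call the reference fraction cytoplasmic, while the sample titles call it total and the design text has it extracted from cells, so it may hold nuclear RNA. The design text speaks of biological replicates, and nothing else says how separate the cultures were.

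The values used are the deposited series table, in which each of 34760 probe sets has 1 value per array on the log2 scale, made by the authors with RMA (background correction, normalization and probe summary), per the submitters' processing notes. The version of RMA and whether the 12 arrays were normalised together are not given in the sources used here. The array medians lay between 6.40 and 6.56, and the quartiles were near one another in all arrays, as normalised arrays are. Because each array was brought to the same scale, a change in the total amount of polysomal RNA or in global translation is not measured. A fold change is relative to the other genes on the same array.

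Probe sets were named through the platform annotation table, which can be old. Of the probe sets, 21640 had 1 gene symbol, 1321 had several and 11799 had none. Symbols were updated through the Entrez gene number with the RefSeq gene table of assembly GRCm38.p6, which held 19855 of the 19937 symbols, and no coordinates are given because the build behind the annotation is not stated. Genes with more than 1 probe set, 954 in number, were represented by the one with the highest mean over the 12 arrays. Genes with a mean below the 40th percentile of all probe sets, a log2 value of 6.0, were left out, which removed 6757 genes and left 13180, of which 12526 are annotated as protein-coding. The level of a gene cannot be set against that of another gene, and the number of arrays limits the precision.

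Group means were fitted to the 13180 genes over all 12 arrays with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes without a trend). The prior had 6.83 degrees of freedom and a standard deviation of 0.117. From this fit came 5 comparisons: 4EGI-1 against control in cytoplasmic RNA, the same in polysomal RNA, the difference of these effects (polysomal minus cytoplasmic, an interaction), and polysomal against cytoplasmic RNA in control cells and in 4EGI-1 cells. P-values were adjusted by Benjamini-Hochberg over the genes tested, with a threshold of 0.05. Errors beside log2 fold changes are standard errors from the fit, and those beside group values are standard deviations of 3 arrays. Adjusted p-values of genes come from limma with this adjustment.

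The design, the settings, 34 gene lists and the rule for the genes to name were chosen before the data were examined. Named are, per treatment comparison and for polysomal against cytoplasmic RNA in control cells, the 8 genes with the largest positive and the 8 with the largest negative change among those that passed and whose arrays did not overlap (for the difference of effects, whose polysomal minus cytoplasmic values, taken between arrays of the same number, did not overlap, which all 385 genes that passed met), leaving out predicted and placeholder symbols (Gm with a number, Rik and LOC symbols), microRNAs, small nucleolar and Cajal body RNAs, olfactory and vomeronasal receptors and ribosomal protein pseudogenes. Up to 3 members with the smallest p-values were added from each list that passed, and Myc, Mcl1, Ccnd3, Odc1, Bcl2, Eif4e, Atf4, Ddit3 and Notch1 were always named. Eif4g1, also on that list, was not analysed here. Lists were tested with camera at a preset correlation of 0.01 between genes, adjusted over the 33 lists with at least 5 tested members. The same test with an estimated correlation, and fry, were run beside it. Camera compares a list with the other genes, while fry asks whether the genes of a list move, on balance, one way. Some genes sit on more than 1 list.

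The scripts were tested on simulated data with the real means and spreads, 13180 genes and 200 changed genes. For a log2 change of 0.5, 65.7% of the changed genes were recovered in cytoplasmic RNA, 71.6% in polysomal RNA and 26.9% in the difference of effects. For a change of 1 these shares were 92.4%, 100% and 87.9%. Of the calls in the difference of effects, 8.43% were false in that simulation, against 4.76% in cytoplasmic and 3.01% in polysomal RNA. The simulation gave both fractions the same spread and held no component shared by genes, while the real cytoplasmic arrays varied more than the polysomal ones. These shares are therefore not the error rates of the real comparisons. In the simulated cytoplasmic comparison camera found the shifted list and called 0 of 50 unshifted lists. With genes drawn independently, this does not show how camera treats lists of correlated genes.

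Alternatives were no filter and a filter at the 60th percentile, the mean of all probe sets of a gene, every probe set as its own feature, quantile normalization over all arrays or within each fraction, centring on array medians, a variance trend, a fit of only the groups compared, the replicate number as a block, a minimum change of 1.5-fold, and each array left out in turn. In a further alternative, arrays of the same treatment and number were a random block, as if from 1 culture, which the labels do not state. For the difference of effects, polysomal minus cytoplasmic values between such arrays were also fitted. Comparisons that share arrays were set against 50 simulations without any effect. Figures were drawn with matplotlib 3.10.9 under Python.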

Results

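The experiment asked which RNAs change in level, and which change in their presence in polysomes, when the eIF4E-eIF4G interaction is blocked in T-ALL cells. Cytoplasmic RNA reports RNA levels. RNA from pooled polysome fractions reports the level and the loading onto several ribosomes together, and the design text gives the cytoplasmic RNA as its reference. Each of the 4 groups (cytoplasmic control, cytoplasmic 4EGI-1, polysomal control, polysomal 4EGI-1) had 3 arrays. P-values measure the spread between these arrays, which may be technical where cultures were not separate.

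Arrays of a group correlated at 0.985 to 0.991 across genes in cytoplasmic control, 0.987 to 0.995 in cytoplasmic 4EGI-1, and 0.996 to 0.997 in both polysomal groups. The median gene had a standard deviation of 0.133 in cytoplasmic control, 0.121 in cytoplasmic 4EGI-1, 0.0745 in polysomal control and 0.0761 in polysomal 4EGI-1. A spread pooled over the groups thus tends to be too small for cytoplasmic and too large for polysomal RNA. Errors and p-values of the main fit tend to be too low in cytoplasmic and too high in polysomal RNA. The first component of the deviations from the group means held 44.8% of the variance within groups and lay in the cytoplasmic arrays. Its scores were 0.06, -0.53 and 0.48 in control arrays 1 to 3 and -0.17, -0.38 and 0.54 in 4EGI-1 arrays 1 to 3, against -0.08 to 0.07 in the polysomal arrays. No 2 arrays held the same values.

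In cytoplasmic RNA, 1325 genes rose and 1027 fell with 4EGI-1 among 13180 tested. Arrdc3, which encodes an arrestin-domain protein, rose by 2.24 ± 0.09 (SE, n = 3 arrays per group) on the log2 scale, a 4.72-fold change (limma, adjusted p = 2.65e-09), and the metallothionein gene Mt2 rose by 1.99 ± 0.17 (limma, adjusted p = 2.14e-06). Kpna2, a nuclear import receptor, fell by 1.44 ± 0.08 (limma, adjusted p = 2.11e-08), and Ccnd1, which encodes cyclin D1, fell by 1.36 ± 0.12 (limma, adjusted p = 2.14e-06). Camera called genes induced by the stress transcription factor ATF4 higher, of which 15 of 34 passed, and genes of mitosis (21 of 30 fell) and of cholesterol synthesis (9 of 20 fell) lower. With an estimated correlation the adjusted p was 0.67 for the ATF4 list and 0.358 for cholesterol synthesis, which did not pass, and 0.00704 for mitosis.

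The other genes with the largest increases were the histone H2B gene H2bc4 (2.33 ± 0.14), Xkrx (1.96 ± 0.14), Kcnrg (1.92 ± 0.13), the zinc finger gene Zfp389 (1.88 ± 0.09), the LIM-domain gene Fhl4 (1.74 ± 0.09) and the noncoding snoRNA host gene Snhg16 (1.68 ± 0.25), with adjusted p-values from 2.11e-08 to 0.00033. The control values of H2bc4 (6.03 ± 0.37, SD), Xkrx (5.83 ± 0.28), Zfp389 (5.09 ± 0.13) and Fhl4 (6.04 ± 0.01) lay near or below the filter level of 6.0, so these genes rose from a dim signal and the sizes of their changes are uncertain. H2bc4 belongs to a family of near-identical genes, and which copy its probe set reports is uncertain. Besides small nucleolar RNAs, which are given with their list, the other largest decreases were those of Sema7a, a membrane-bound semaphorin (-1.43 ± 0.10), Tmem50b (-1.32 ± 0.09), Ccnf, which encodes cyclin F (-1.29 ± 0.13), the LIM-domain gene Crip1 (-1.27 ± 0.11), the lipid transporter gene Mfsd2a (-1.22 ± 0.18) and Tmem229b (-1.21 ± 0.15), with adjusted p-values from 3.27e-07 to 0.000323. At least 1.5-fold changes were seen in 420 of the genes that rose and 174 of those that fell. Fitted on the 6 cytoplasmic arrays alone, where the spread comes from these arrays only, 731 genes rose and 369 fell. The number of genes that fell was 633, 588 and 668 without 4EGI-1 array 1, 4EGI-1 array 2 or control array 3 and 1583 and 1622 without control array 2 or 4EGI-1 array 3, and the number that rose was 869 without 4EGI-1 array 1.

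Of 34 tested ATF4 targets in cytoplasmic RNA, 15 rose, 0 fell and 19 did not pass (19 rose and 1 fell adjusted over the list alone), with a median change of 0.28 (camera, adjusted p = 4.13e-09; adjusted p = 0.67 with an estimated correlation). Among them were Slc7a11, the cystine transporter (1.12 ± 0.09), Ddit3, which encodes the stress transcription factor CHOP (0.87 ± 0.09), and Chac1, which encodes a glutathione-degrading enzyme (1.34 ± 0.14), with adjusted p-values from 1.03e-06 to 1.42e-05. Of 30 genes of G2/M and mitosis, 0 rose and 21 fell (24 fell adjusted over the list alone), with a median of -0.41 (camera, adjusted p = 9.47e-15). This call alone among the lists held with an estimated correlation in this comparison (adjusted p = 0.00704). The kinase-binding protein gene Cks2 (-1.15 ± 0.08), the mitotic kinase gene Aurka (-1.12 ± 0.11) and the kinesin gene Kif23 (-0.79 ± 0.08) fell, with adjusted p-values from 4.95e-07 to 9.35e-06. Of 20 cholesterol synthesis genes, 9 fell and 0 rose (11 fell adjusted over the list alone), with a median of -0.29 (camera, adjusted p = 6.67e-06; adjusted p = 0.358 with an estimated correlation). They included Hmgcs1 (-0.66 ± 0.07) and Sqle (-0.62 ± 0.07), enzymes of the pathway, and Insig1 (-0.79 ± 0.11), its regulator in the endoplasmic reticulum.

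Small nucleolar RNAs, which guide modification of ribosomal RNA, fell in 10 of 41 cases and rose in 0 (12 fell adjusted over the list alone), with a median of -0.21 (camera, adjusted p = 0.00161; adjusted p = 0.67 with an estimated correlation). Snora73b (-1.11 ± 0.08), Snord52 (-1.25 ± 0.12) and Snora73a (-0.89 ± 0.11) had the smallest p-values. Of 80 nuclear-encoded respiratory chain genes, 7 fell and 0 rose (6 fell adjusted over the list alone), with a median of -0.12 (camera, adjusted p = 0.00812; adjusted p = 0.67 with an estimated correlation). Uqcrh of complex III (-0.52 ± 0.10), Sdhd of complex II (-0.57 ± 0.11) and Ndufb3 of complex I (-0.49 ± 0.10) were among them. Of 27 T cell identity genes, 3 fell and 0 rose (3 adjusted over the list alone), with a median of -0.14 (camera, adjusted p = 0.0227; adjusted p = 0.67 with an estimated correlation). These were the surface receptor genes Cd27 (-0.70 ± 0.13), Cd2 (-0.55 ± 0.12) and Cd3e (-0.32 ± 0.08). The camera call of the small nucleolar RNAs ended without 4EGI-1 array 3 (adjusted p = 0.0982), that of the respiratory chain without control array 3 (0.0649) or 4EGI-1 array 3 (0.0542), and that of T cell identity without control array 3 (0.0649) or 4EGI-1 array 1 (0.0693). In the fit of the 6 cytoplasmic arrays alone Cd3e had an adjusted p of 0.0802 (limma).

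In polysomal RNA, 1717 genes rose and 1599 fell with 4EGI-1. Snhg16 rose by 2.01 ± 0.25 (limma, adjusted p = 3.68e-05), Arrdc3 by 1.91 ± 0.09 (limma, adjusted p = 2.52e-08), and Prpf8, which encodes a core protein of the spliceosome, by 1.72 ± 0.11 (limma, adjusted p = 9.87e-08). Tmem50b fell by 1.61 ± 0.09 (limma, adjusted p = 3.4e-08). Crip1 fell by 1.56 ± 0.11 (limma, adjusted p = 1.99e-07). Camera called 9 lists at its preset correlation, among them ATF4 targets, aminoacyl-tRNA synthetases and ribosome biogenesis on the higher side and the respiratory chain, ribosomal proteins and cholesterol synthesis on the lower. None of the 9 calls held with an estimated correlation (adjusted p from 0.359 to 0.477).

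The other largest increases were those of H2bc4 (1.96 ± 0.14), the amylase gene Amy1 (1.85 ± 0.10), Xkrx (1.83 ± 0.14), Zfp389 (1.76 ± 0.09) and the amino acid transporter gene Slc7a7 (1.75 ± 0.11), with adjusted p-values from 3.4e-08 to 6.29e-07. The polysomal control values of Zfp389 (5.64 ± 0.04, SD), Amy1 (6.08 ± 0.17), Slc7a7 (6.13 ± 0.19) and Xkrx (6.45 ± 0.14) lay near or below the filter level of 6.0, so the sizes of these changes are uncertain. Amy1 has near-identical copies that its probe set cannot be assumed to part. Further decreases were those of Ccnf (-1.39 ± 0.13), the lymphocyte surface gene Cd52 (-1.31 ± 0.13), Cks2 (-1.31 ± 0.08), the spindle gene Fam83d (-1.31 ± 0.09), Tmsb4x, which encodes an actin-binding thymosin (-1.24 ± 0.14), and Mrpl42, which encodes a protein of the mitochondrial ribosome (-1.19 ± 0.10), with adjusted p-values from 9.87e-08 to 1.1e-05. At least 1.5-fold changes were seen in 604 of the genes that rose and 279 of those that fell. The fit of the 6 polysomal arrays alone counted 2346 genes that rose and 2685 that fell.

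Of the 34 ATF4 targets, 17 rose and 0 fell in polysomal RNA (18 rose and 2 fell adjusted over the list alone), with a median of 0.35 (camera, adjusted p = 4.32e-08; adjusted p = 0.477 with an estimated correlation). The cystine transporter gene Slc7a11 (1.17 ± 0.09), the amino acid transporter gene Slc7a3 (0.94 ± 0.08) and Ddit3 (0.86 ± 0.09) led them. Of 18 cytosolic aminoacyl-tRNA synthetases, 7 rose and 0 fell (8 rose adjusted over the list alone), with a median of 0.18 (camera, adjusted p = 4.69e-05; adjusted p = 0.359 with an estimated correlation). Lars (1.47 ± 0.08), Eprs (1.16 ± 0.07) and Tars (0.68 ± 0.08), which charge tRNAs with leucine, glutamate and proline, and threonine, had adjusted p-values from 3.4e-08 to 1.86e-05. Of 40 ribosome biogenesis genes, 14 rose and 4 fell (15 and 4 adjusted over the list alone), with a median of 0.06 (camera, adjusted p = 0.0197; adjusted p = 0.477 with an estimated correlation). The nucleolar genes Heatr1 (1.23 ± 0.08) and Mybbp1a (1.48 ± 0.15) and the RNA polymerase I subunit gene Polr1a (1.10 ± 0.07) rose.

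Of 80 respiratory chain genes, 46 fell and 1 rose in polysomal RNA (52 and 1 adjusted over the list alone), with a median of -0.33 (camera, adjusted p = 7.82e-12; adjusted p = 0.359 with an estimated correlation). Atp5k of the ATP synthase (-0.82 ± 0.08), Uqcrh (-0.80 ± 0.10) and Ndufb3 (-0.85 ± 0.10) had the smallest p-values. Of 54 ribosomal protein genes, 17 fell and 0 rose (17 adjusted over the list alone), with a median of -0.16 (camera, adjusted p = 0.000108; adjusted p = 0.416 with an estimated correlation). Rps28 (-0.69 ± 0.10), Fau (-0.52 ± 0.09) and Rps14 (-0.49 ± 0.09), all of the small subunit, were among them, and ribosomal protein genes have many processed copies whose signal a probe set can share. Of 20 cholesterol synthesis genes, 12 fell and 0 rose (12 adjusted over the list alone), with a median of -0.28 (camera, adjusted p = 8.23e-05; adjusted p = 0.396 with an estimated correlation). The pathway enzyme genes Sqle (-0.62 ± 0.07), Msmo1 (-0.53 ± 0.09) and Hmgcs1 (-0.41 ± 0.07) fell. Small nucleolar RNAs fell in 10 of 41 cases and rose in 1 (10 and 1 adjusted over the list alone), with a median of -0.22 (camera, adjusted p = 0.00294; adjusted p = 0.416 with an estimated correlation). Among them Snora73b (-0.62 ± 0.08), Snord52 (-0.94 ± 0.12) and Snord14e (-0.78 ± 0.16) fell.

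The mRNAs listed as sensitive to eIF4E included 11 of 24 that fell and 3 that rose in polysomal RNA (11 and 3 adjusted over the list alone), with a median of -0.19 (camera, adjusted p = 0.0101; adjusted p = 0.416 with an estimated correlation). The cyclin genes Ccnd1 (-1.18 ± 0.12) and Ccnd2 (-0.78 ± 0.10) and the apoptosis inhibitor gene Birc5 (-0.62 ± 0.11) fell. Of 30 genes of G2/M and mitosis, 15 fell and 6 rose (16 and 6 adjusted over the list alone), with a median of -0.26 (camera, adjusted p = 0.0392; adjusted p = 0.416 with an estimated correlation). Cks2 (-1.31 ± 0.08) and the mitotic kinase gene Cdk1 (-0.69 ± 0.09) fell, while Top2a, which encodes a DNA topoisomerase, rose by 0.82 ± 0.08. With the mean of all its probe sets Top2a had a change of 0.31 and an adjusted p of 0.0727 (limma), so its probe sets disagreed. The call of G2/M and mitosis ended without polysomal control array 3 (adjusted p = 0.0668) or polysomal 4EGI-1 array 2 (0.0843).

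**Figure D1:**
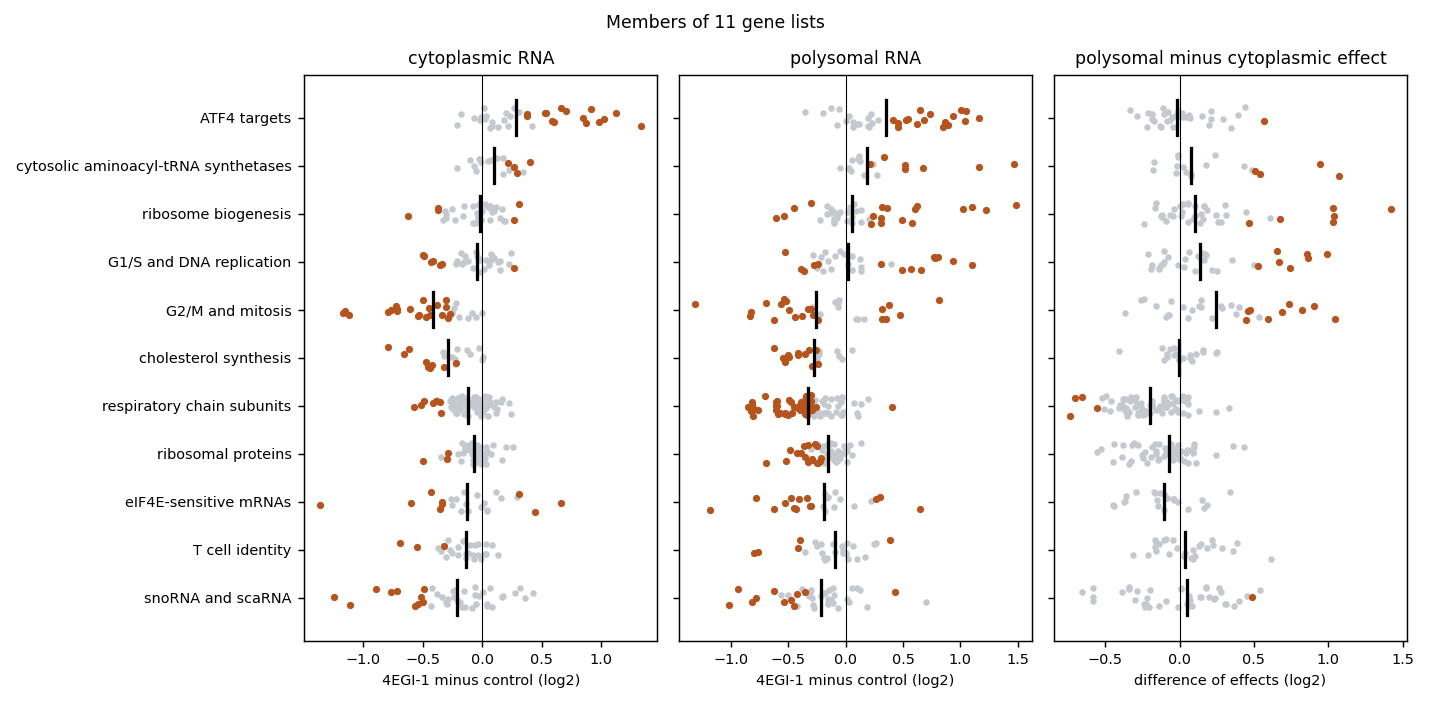
Change of each tested member of 11 gene lists, on the log2 scale, for 4EGI-1 minus control in cytoplasmic RNA (left), in polysomal RNA (middle) and for the difference of these effects (right). Orange points passed an adjusted p of 0.05, grey points did not, and the black bar is the list's median, such as 0.28 and 0.35 for ATF4 targets and -0.12 and -0.33 for respiratory chain subunits in the 2 fractions; vertical scatter within a list only separates the points.

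Genes named in advance showed mixed results. Ddit3 rose by 0.87 ± 0.09 in cytoplasmic and 0.86 ± 0.09 in polysomal RNA. Atf4, whose translation is regulated by upstream reading frames, rose in polysomal RNA (0.41 ± 0.08; limma, adjusted p = 0.00143) and had a change of 0.22 ± 0.08 in cytoplasmic RNA (limma, adjusted p = 0.0817). The latter passed after quantile normalization of all arrays (0.0418), within fractions (0.0405) or centring on array medians (0.0358). Ccnd3, which encodes cyclin D3, fell by 0.60 ± 0.12 in cytoplasmic RNA (limma, adjusted p = 0.00244) and fell by 0.45 ± 0.12 in polysomal RNA (0.0106). Odc1, the first enzyme of polyamine synthesis, fell in polysomal RNA (-0.33 ± 0.09; limma, adjusted p = 0.0108) and had a change of 0.04 ± 0.09 in cytoplasmic RNA (0.807). Eif4e itself fell in polysomal RNA (-0.30 ± 0.08; limma, adjusted p = 0.0108) with a cytoplasmic change of -0.06 ± 0.08 (0.655), and its polysomal value with the mean of all its probe sets was -0.25 (0.0792). Without polysomal control array 1 the adjusted p was 0.0612 for Ccnd3, 0.0516 for Odc1 and 0.0528 for Eif4e in polysomal RNA, and without polysomal 4EGI-1 array 3 it was 0.052 for Eif4e.

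The oncogene Myc had a change of -0.12 ± 0.13 in cytoplasmic RNA (limma, adjusted p = 0.579) and 0.22 ± 0.13 in polysomal RNA (0.268), and the receptor gene Notch1 had -0.21 ± 0.14 (0.34) and 0.32 ± 0.14 (0.125). The survival genes Mcl1 (-0.16 ± 0.13 and -0.20 ± 0.13) and Bcl2 (0.11 ± 0.09 and -0.05 ± 0.09) did not pass in either fraction. In the fit of the 6 polysomal arrays alone Myc (adjusted p = 0.0174, limma) and Notch1 (0.00211) passed with the same changes. Without cytoplasmic 4EGI-1 array 3 the cytoplasmic change of Notch1 was -0.41 (limma, adjusted p = 0.0172) and its polysomal change passed (0.0283).

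**Figure D2:**
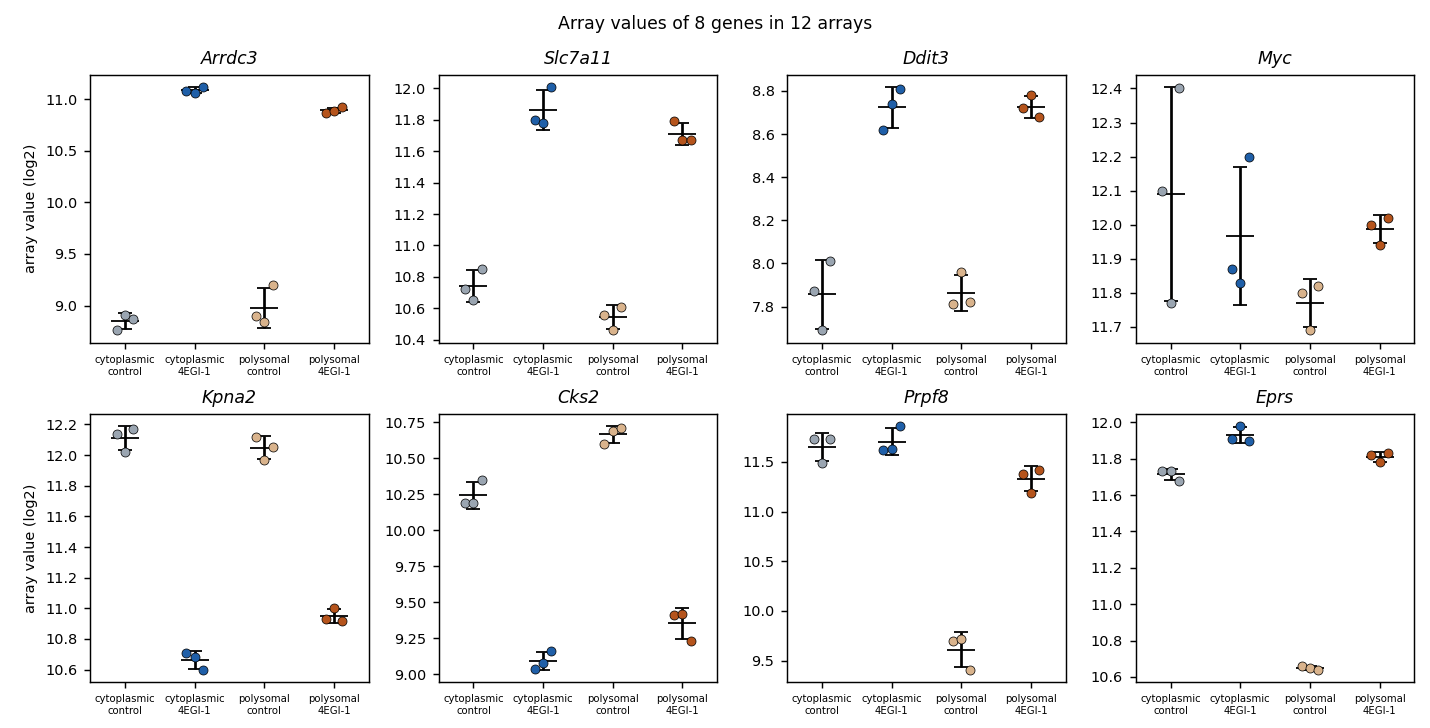
Array values on the log2 scale of 8 genes in the 4 groups, with 1 point per array (3 per group) and a bar at the mean with its standard deviation; the vertical axes differ and do not start at 0. Arrdc3, Slc7a11 and Ddit3 are higher and Kpna2 and Cks2 lower with 4EGI-1 in both fractions, Myc overlaps between groups in cytoplasmic RNA, and Prpf8 and Eprs are low only in polysomal control arrays (9.61 ± 0.17 and 10.65 ± 0.01).

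The fractions changed in the same direction for most genes that passed in both. Rising in both were 877 genes, against 172.6 for independent lists, 622 fell in both, against 124.6, and 20 went opposite ways. These comparisons share no arrays. They do share 1 estimate of the spread per gene, and the fractions may come from the same cultures, so the lists are not fully independent. Across genes, which are not independent replicates, the fold changes correlated at 0.699.

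The remaining lists did not pass camera in either fraction. Genes of each that rose and fell are counted first in cytoplasmic and then in polysomal RNA. Other mRNAs with a 5-prime terminal oligopyrimidine tract (22 tested, medians -0.08 and -0.05) had 0 up and 1 down, then 2 up and 2 down (0 and 0, then 2 and 1 adjusted over the list alone). Genes of eIF4F and its regulators (15 tested, medians -0.08 and -0.17) had 0 up and 2 down, then 2 up and 5 down (0 and 2, then 2 and 6 adjusted over the list alone). Endoplasmic reticulum chaperones (30 tested, medians -0.07 and -0.05) had 3 up and 6 down, then 3 up and 4 down (3 and 7, then 3 and 4 adjusted over the list alone). Heat shock proteins (17 tested, medians -0.02 and -0.03) had 0 up and 1 down, then 2 up and 3 down (0 and 1, then 2 and 3 adjusted over the list alone). Targets of the oxidative stress factor NRF2 (21 tested, medians -0.12 and -0.09) had 1 up and 4 down, then 2 up and 2 down (1 and 6, then 2 and 2 adjusted over the list alone). Immediate early genes (29 tested, medians -0.06 and -0.05) had 2 up and 4 down, then 2 up and 6 down (3 and 6, then 2 and 6 adjusted over the list alone). Targets of p53 (16 tested, medians -0.02 and -0.17) had 3 up and 5 down, then 3 up and 6 down (3 and 5, then 3 and 8 adjusted over the list alone). The BCL2 family of apoptosis regulators (17 tested, medians -0.04 and -0.12) had 1 up and 2 down, then 1 up and 4 down (1 and 2, then 1 and 4 adjusted over the list alone). NOTCH targets (18 tested, medians -0.16 and -0.04) had 2 up and 4 down, then 2 up and 5 down (2 and 4, then 4 and 6 adjusted over the list alone). NF-kB targets (16 tested, medians -0.02 and -0.05) had 1 up and 3 down, then 2 up and 3 down (1 and 3, then 2 and 3 adjusted over the list alone). FOXO targets (22 tested, medians -0.06 and 0.05) had 2 up and 5 down, then 3 up and 4 down (3 and 5, then 4 and 4 adjusted over the list alone). Interferon response genes (12 tested, medians -0.14 and 0.01) had 0 up and 2 down, then 2 up and 0 down (2 and 4, then 2 and 0 adjusted over the list alone).

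Glycolysis genes (16 tested, medians -0.10 and -0.12) had 1 up and 4 down, then 1 up and 3 down (1 and 5, then 2 and 4 adjusted over the list alone). Proteasome subunits (34 tested, medians -0.09 and -0.06) had 0 up and 0 down, then 1 up and 4 down (0 and 0, then 1 and 4 adjusted over the list alone). Autophagy and lysosome genes (31 tested, medians -0.06 and -0.09) had 3 up and 2 down, then 2 up and 5 down (4 and 2, then 2 and 5 adjusted over the list alone). Histones (25 tested, medians 0.04 and -0.01) had 5 up and 1 down, then 4 up and 2 down (6 and 2, then 4 and 2 adjusted over the list alone). Long noncoding RNAs (10 tested, medians 0.11 and 0.04) had 1 up and 1 down, then 1 up and 1 down (4 and 1, then 1 and 1 adjusted over the list alone). Olfactory receptors, which T cells are not known to use, (87 tested, medians 0.01 and -0.02) had 7 up and 0 down, then 8 up and 1 down (7 and 0, then 7 and 0 adjusted over the list alone). Markers of B cells (6 tested, medians -0.03 and 0.03) had 1 up and 0 down, then 1 up and 0 down (1 and 0, then 1 and 0 adjusted over the list alone). Markers of myeloid cells (7 tested, medians -0.04 and 0.09) had 2 up and 0 down, then 1 up and 0 down (2 and 0, then 1 and 0 adjusted over the list alone). Markers of erythroid cells (5 tested, medians 0.00 and 0.07) had 0 up and 1 down, then 0 up and 0 down (1 and 1, then 0 and 0 adjusted over the list alone). Markers of stroma (9 tested, medians -0.08 and -0.04) had 0 up and 2 down, then 0 up and 0 down (0 and 2, then 0 and 0 adjusted over the list alone). Median and test differed in sign for B cell markers (mean 0.11) and myeloid markers (mean 0.10) in cytoplasmic RNA. They also did for histones (mean 0.09) and olfactory receptors (mean 0.05) in polysomal RNA.

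Lists that passed in another comparison did not pass everywhere. In cytoplasmic RNA, ribosomal proteins (median -0.07, 0 up and 3 down, 0 and 0 adjusted over the list alone) did not pass. Nor did eIF4E-sensitive mRNAs (median -0.13, 3 up and 6 down, 4 and 7 adjusted over the list alone) and aminoacyl-tRNA synthetases (median 0.10, 4 up and 0 down, 6 and 0 adjusted over the list alone). The same held for ribosome biogenesis (median -0.02, 2 up and 3 down, 2 and 2 adjusted over the list alone). In polysomal RNA T cell identity (median -0.09, 1 up and 4 down, 1 and 4 adjusted over the list alone) did not pass. Genes of G1/S and DNA replication (median -0.04, 1 up and 6 down, 1 and 6 adjusted over the list alone) did not pass in cytoplasmic RNA, nor in polysomal RNA (median 0.02, 9 up and 5 down, 9 and 7 adjusted over the list alone). The lowest adjusted p of camera among lists that did not pass was 0.121, for the synthetases, in cytoplasmic and 0.205, for eIF4F, in polysomal RNA. Of the mitochondrially encoded RNAs only COX2 and ND3 were tested. ND3 fell in polysomal RNA (-0.63 ± 0.08; limma, adjusted p = 4.3e-05), with a cytoplasmic change of -0.11 ± 0.08 (0.38) and a difference of effects of -0.52 ± 0.12 (0.023). COX2 had changes of -0.22 ± 0.13 in cytoplasmic (0.294) and -0.22 ± 0.13 in polysomal RNA (0.266).

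The interaction asked which RNAs changed in polysomes beyond their change in the cytoplasm. The effect of 4EGI-1 was higher in polysomal than in cytoplasmic RNA for 305 genes and lower for 80. Prpf8 differed by 1.67 ± 0.15 (limma, adjusted p = 5.12e-05), the clathrin heavy chain gene Cltc by 1.49 ± 0.12 (3.44e-05) and Dock2, which encodes an activator of the GTPase Rac in lymphocytes, by 1.29 ± 0.12 (6.55e-05). On the lower side, Mrpl42 differed by -0.81 ± 0.14 (limma, adjusted p = 0.0039) and Fth1, which encodes the ferritin heavy chain, by -0.73 ± 0.12 (0.00268). At its preset correlation camera called mitosis, DNA replication, ribosome biogenesis and aminoacyl-tRNA synthetases higher, and the respiratory chain and ribosomal proteins lower. None of these calls held with an estimated correlation (adjusted p from 0.0615 to 0.643), and 0 of 54 ribosomal protein genes passed.

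Prpf8 had polysomal values of 9.61 ± 0.17 (SD) in control and 11.33 ± 0.12 in 4EGI-1 cells at cytoplasmic values of 11.65 ± 0.14 and 11.70 ± 0.13. The 305 genes had a median polysomal effect of 0.68 at a median cytoplasmic effect of -0.01, and the 80 genes had medians of -0.43 and 0.16. The other largest positive differences were those of the histone gene H2bc8 (1.55 ± 0.23), Mybbp1a (1.42 ± 0.21), the Golgi protein gene Glg1 (1.35 ± 0.16), Cad, which encodes an enzyme of pyrimidine synthesis (1.27 ± 0.20), and the folate enzyme gene Mthfd1 (1.26 ± 0.18), with adjusted p-values from 0.000224 to 0.00193. H2bc8 differed mostly by its cytoplasmic values, 8.78 ± 0.07 in control and 7.67 ± 0.30 in 4EGI-1 cells. Its polysomal values were 6.88 ± 0.34 and 7.33 ± 0.20, and it has near-identical copies. The other negative differences were those of Slc10a1, a bile acid transporter (-0.80 ± 0.16), Mrpl33 of the mitochondrial ribosome (-0.78 ± 0.19), the membrane traffic gene Bet1 (-0.74 ± 0.13), Ndufa5 of complex I (-0.74 ± 0.19), the glycosylation enzyme gene Galnt1 (-0.72 ± 0.15) and the centriole gene Sclt1 (-0.71 ± 0.15), with adjusted p-values from 0.00565 to 0.0473. The polysomal control value of Slc10a1 (5.94 ± 0.16, SD) lay below the filter level of 6.0. The calls of Mrpl33 and Ndufa5 held with 1 array left out only where that was cytoplasmic control array 2 or cytoplasmic 4EGI-1 array 3 (highest adjusted p otherwise 0.12 and 0.143, limma). Both calls also ended without the filter on low values (limma, adjusted p = 0.0776 and 0.0971), with every probe set as its own feature (0.0855 and 0.103), after quantile normalization of all arrays (0.0535 and 0.0773) and after centring on array medians (0.0749 and 0.0838), and that of Ndufa5 after quantile normalization within fractions (0.0728). That of Sclt1 ended without cytoplasmic control array 1 (0.0591), cytoplasmic 4EGI-1 arrays 1 (0.0593) or 2 (0.0512), polysomal control arrays 1 (0.058) or 3 (0.0521), or polysomal 4EGI-1 array 3 (0.0697). That of Galnt1 ended without cytoplasmic 4EGI-1 array 1 (0.05), polysomal control array 2 (0.0592), or polysomal 4EGI-1 arrays 1 (0.0573) or 3 (0.0548). That of Slc10a1 ended without polysomal 4EGI-1 array 1 (0.0503).

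The count of 305 was 179 without polysomal control array 1, 194 without polysomal control array 2, 180 without polysomal 4EGI-1 array 1 and 179 without polysomal 4EGI-1 array 3. The count of 80 was 32, 22 and 31 without polysomal control arrays 1, 2 or 3, 28, 40 and 21 without polysomal 4EGI-1 arrays 1, 2 or 3, 32 and 259 without cytoplasmic control arrays 1 or 2, and 19 and 211 without cytoplasmic 4EGI-1 arrays 1 or 3. Of the 305 genes, 284 also rose in polysomal RNA, against 39.7 for independent lists, and 292 were lower in polysomal than in cytoplasmic RNA of control cells, against 37.3. Of the 80 genes, 60 fell in polysomal RNA, against 9.7, and 64 were higher in polysomal RNA of control cells, against 13.4. These comparisons share arrays: with no effect, simulated differences correlated with the polysomal against cytoplasmic values of control cells at -0.71 and had a covariance of -0.0127, against an observed -0.65 and -0.0478. With the polysomal effects they correlated at 0.52 with no effect, with a covariance of 0.00682, against an observed 0.50 and 0.0346. The simulated overlap of calls with the control-cell comparison was 0.1 genes on average. A simulation without effects leaves almost nothing to call, so this overlap is no baseline for the counts above. Part of the excess may come from the shared arrays.

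**Figure D3:**
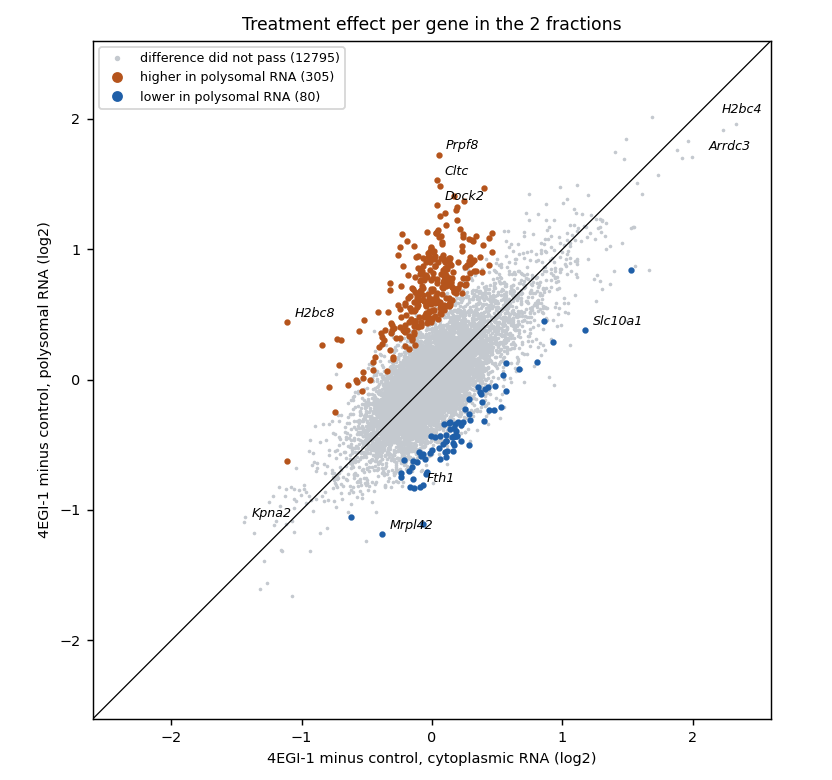
Treatment effect of each of 13180 genes on the log2 scale in cytoplasmic (horizontal) and polysomal RNA (vertical); the line marks equal effects. Orange points are the 305 genes with a higher and blue points the 80 genes with a lower effect in polysomal RNA, and most orange points lie near a cytoplasmic effect of 0, with a median of -0.01.

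Of 30 genes of G2/M and mitosis, 9 had a higher and 0 a lower effect in polysomal RNA (11 adjusted over the list alone). The median difference was 0.25 (camera, adjusted p = 8.61e-08; adjusted p = 0.0615 with an estimated correlation). Higher were the kinesin genes Kif2c (1.04 ± 0.12) and Kif23 (0.74 ± 0.11) and Top2a (0.90 ± 0.11). The probe sets of Top2a disagreed in polysomal RNA, and its value here is that of the brightest one. Kif23 fell in cytoplasmic RNA from 10.84 ± 0.11 to 10.05 ± 0.10 (SD) at polysomal values of 10.27 ± 0.01 and 10.21 ± 0.04. Kif2c, too, differed mostly by its cytoplasmic values, 10.01 ± 0.07 and 9.28 ± 0.14, at polysomal values of 9.23 ± 0.07 and 9.54 ± 0.04. The list's median effects were -0.41 in cytoplasmic and -0.26 in polysomal RNA. Its positive difference is thus, at the median, a smaller fall in polysomal RNA, although 6 of 30 genes rose there. Of 32 genes of G1/S and DNA replication, 7 were higher and 0 lower (8 adjusted over the list alone). The median was 0.14 (camera, adjusted p = 0.000308; adjusted p = 0.643 with an estimated correlation). The nucleotide reductase gene Rrm1 (0.99 ± 0.11), the chromatin gene Uhrf1 (0.86 ± 0.11) and the helicase gene Mcm4 (0.67 ± 0.12) were higher. Of 40 ribosome biogenesis genes, 6 were higher and 0 lower (7 adjusted over the list alone). The median was 0.10 (camera, adjusted p = 3.42e-05; adjusted p = 0.334 with an estimated correlation). Higher were Polr1a (1.04 ± 0.10) and the nucleolar genes Heatr1 (1.03 ± 0.11) and Utp20 (1.03 ± 0.15). Of 18 aminoacyl-tRNA synthetases, 4 were higher and 0 lower (5 adjusted over the list alone). The median was 0.08 (camera, adjusted p = 0.000308; adjusted p = 0.334 with an estimated correlation), and the smallest p-values were those of Eprs (0.95 ± 0.09), Lars (1.07 ± 0.12) and the isoleucine enzyme gene Iars (0.54 ± 0.11). The call of Iars ended without cytoplasmic 4EGI-1 array 1 (limma, adjusted p = 0.0514), polysomal control array 2 (0.0566) or polysomal 4EGI-1 array 1 (0.0531).

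Of 80 respiratory chain genes, 4 had a lower and 0 a higher effect in polysomal RNA (7 adjusted over the list alone). The median difference was -0.20 (camera, adjusted p = 1.01e-08; adjusted p = 0.334 with an estimated correlation). Atp5k (-0.66 ± 0.12), Ndufb2 (-0.70 ± 0.14) and Ndufs6 (-0.55 ± 0.14), the last pair of complex I, had the smallest p-values. The call of Ndufs6 held with 1 array left out only where that was cytoplasmic control array 2 or cytoplasmic 4EGI-1 array 3 (highest adjusted p otherwise 0.149, limma). It ended too without the filter (0.0994), with every probe set as its own feature (0.0891), after quantile normalization of all arrays (0.0612) or within fractions (0.0537), and after centring on array medians (0.0943). Of 54 ribosomal protein genes, 0 passed (4 lower adjusted over the list alone). The median was -0.07 (camera, adjusted p = 0.00594; adjusted p = 0.643 with an estimated correlation). That camera call ended without cytoplasmic control array 2 (adjusted p = 0.0672) or cytoplasmic 4EGI-1 array 3 (0.122). The mRNAs listed as sensitive to eIF4E had a median difference of -0.10 with 0 of 24 passing (camera, adjusted p = 0.0717), and ATF4 targets had a median of -0.02, a mean of 0.02 and a test direction upward (0.756). Myc (0.34 ± 0.19; limma, adjusted p = 0.465), Mcl1 (-0.04 ± 0.19; 0.96), Ccnd3 (0.15 ± 0.17; 0.785), Odc1 (-0.37 ± 0.12; 0.158), and Bcl2 (-0.16 ± 0.13; 0.657) did not pass. Neither did Eif4e (-0.24 ± 0.11; 0.365), Atf4 (0.20 ± 0.11; 0.497), Ddit3 (0.00 ± 0.13; 0.999) and Notch1 (0.53 ± 0.20; 0.228). Notch1 passed without cytoplasmic 4EGI-1 array 3 (0.73; 0.0118). In settings chosen after the data were seen, Myc and Notch1 passed without cytoplasmic control array 2 and cytoplasmic 4EGI-1 array 3 together (limma, adjusted p = 0.00608 and 0.000451). The cytoplasmic arrays left then differed between treatments along the first within-group component, so these calls may reflect it. Myc and Notch1 also passed, with Odc1, with that component as a covariate (limma, adjusted p = 0.0272, 0.0251 and 0.0316). This covariate comes from the same arrays and takes out spread without moving fold changes, so added calls are built in.

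Control cells show which RNAs were over- or underrepresented in polysomes without the inhibitor. Higher in polysomal RNA were 2205 genes and lower 1614. Atxn1, which encodes a transcriptional regulator, was higher by 2.34 ± 0.26 (limma, adjusted p = 1.4e-05), and Ly96, a partner of the receptor TLR4, by 2.04 ± 0.17 (9.76e-07). The cytoplasmic control value of Ly96 was 5.51 ± 0.37 (SD), below the filter level of 6.0, so the size of its change is uncertain. The noncoding RNAs Rpph1, the RNA of ribonuclease P, and Rn7sk, a regulator of transcription elongation, were lower by -2.43 ± 0.11 and -2.38 ± 0.11 (limma, adjusted p = 3.4e-09 for both). Small nucleolar RNAs, which the naming by size leaves out, are given with their list. Prpf8 was lower by -2.04 ± 0.11 and Cad by -2.12 ± 0.14.

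Also higher were Cetn2, Hmgn5, Sarnp, Stxbp4, Zfp825 and Ift74, by 1.26 to 1.38, and also lower were the fatty acid synthase gene Fasn (-2.0 ± 0.17), Rpl12 (-1.96 ± 0.14), H2bc8 (-1.90 ± 0.16) and the spliceosome helicase gene Snrnp200 (-1.89 ± 0.08). Small nucleolar RNAs were lower in 32 of 41 cases and higher in 0 (34 lower adjusted over the list alone). The median was -0.86 (camera, adjusted p = 6.47e-19; adjusted p = 0.0272 with an estimated correlation). Examples were Snord16a (-2.15 ± 0.10), Snora73b (-1.36 ± 0.08) and Snord87 (-2.17 ± 0.14), the last with a dim polysomal value of 5.72 ± 0.11 (SD). Of 10 long noncoding RNAs, 5 were lower and 0 higher (7 lower adjusted over the list alone). The median was -0.41 (camera, adjusted p = 0.000253; adjusted p = 0.0432 with an estimated correlation). Rmrp (-1.10 ± 0.10) was among the lower. Respiratory chain genes were higher in 34 of 80 cases and lower in 4 (36 and 4 adjusted over the list alone). The median was 0.22 (camera, adjusted p = 1.23e-06; adjusted p = 0.61 with an estimated correlation). Ndufa5 (1.19 ± 0.13), Ndufb3 (0.86 ± 0.10) and Cox7a2 (0.94 ± 0.12) were higher. Proteasome genes were higher in 15 of 34 cases and lower in 1 (15 and 1 adjusted over the list alone). The median was 0.17 (camera, adjusted p = 0.000253; adjusted p = 0.789 with an estimated correlation). Psma5 (1.15 ± 0.14) and Psma6 (0.58 ± 0.08) were higher and Psmd1 (-0.45 ± 0.07) lower. Histone genes were higher in 20 of 25 cases and lower in 2 (21 and 2 adjusted over the list alone). The median was 0.51 (camera, adjusted p = 1.23e-06; adjusted p = 0.61 with an estimated correlation). H1f1 (0.76 ± 0.09) was higher and H1f2 (-1.05 ± 0.09) lower.

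In 4EGI-1 cells 1260 genes were higher and 942 lower in polysomal than in cytoplasmic RNA. Small nucleolar RNAs were again lower, in 33 of 41 cases and higher in 0 (35 and 1 adjusted over the list alone). The median was -0.91 (camera, adjusted p = 3.37e-27; adjusted p = 0.00533 with an estimated correlation). So were 5 of 10 long noncoding RNAs (6 adjusted over the list alone). The median was -0.36 (camera, adjusted p = 1.53e-07; adjusted p = 0.00533 with an estimated correlation). Ribosomal protein genes were lower in 16 of 54 cases and higher in 2 (21 and 2 adjusted over the list alone). The median was -0.14 (camera, adjusted p = 1.48e-06; adjusted p = 0.314 with an estimated correlation). Histones were higher in 11 of 25 cases (18 adjusted over the list alone). The median was 0.36 (camera, adjusted p = 1.55e-07; adjusted p = 0.397 with an estimated correlation). The proteasome was higher in 13 of 34 cases (17 adjusted over the list alone). The median was 0.23 (camera, adjusted p = 1.2e-06; adjusted p = 0.422 with an estimated correlation). Genes of G2/M and mitosis were higher in 10 of 30 cases and lower in 1 (13 and 2 adjusted over the list alone). The median was 0.21 (camera, adjusted p = 0.000132; adjusted p = 0.121 with an estimated correlation). Respiratory chain genes had a median of 0.07 and did not pass camera (adjusted p = 0.419), against 0.22 in control cells. The number of genes that were higher was 549 and 676, and that of lower genes 497 and 552, without polysomal 4EGI-1 arrays 1 or 3, and the number of lower genes was 623 without cytoplasmic 4EGI-1 array 1.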

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

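The test of other groupings of the arrays was chosen after the result was seen, and the other tests in this part before. The lists of large and small proteins were drawn up after the largest changes had been seen, and they leave those genes out.

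The effect of 4EGI-1 was higher in polysomal than in cytoplasmic RNA for 305 genes and lower for 80, by the test of the interaction (limma, Benjamini-Hochberg). Higher were Prpf8 (1.67 on the log2 scale), H2bc8 (1.55), Cltc (1.49), Mybbp1a (1.42), Glg1 (1.35), Dock2 (1.29), Cad (1.27) and Mthfd1 (1.26). Higher too were the tRNA synthetase genes Lars (1.07), Eprs (0.95) and Iars (0.54), and the ribosome biogenesis genes Polr1a (1.04), Heatr1 (1.03) and Utp20 (1.03). Genes of DNA replication and mitosis among them were Rrm1 (0.99), Uhrf1 (0.86), Mcm4 (0.67), Kif2c (1.04), Top2a (0.90) and Kif23 (0.74). The probe sets of Top2a disagreed in polysomal RNA, and Kif2c and Kif23 differed mostly by a fall in cytoplasmic RNA. Lower were Mrpl42 (-0.81), Slc10a1 (-0.80), Mrpl33 (-0.78), Bet1 (-0.74), Ndufa5 (-0.74), Fth1 (-0.73), Galnt1 (-0.72), Sclt1 (-0.71), Ndufb2 (-0.70), Atp5k (-0.66) and Ndufs6 (-0.55). The lists that camera called at its preset correlation had median differences of 0.25 for G2/M and mitosis, 0.14 for G1/S and DNA replication, 0.10 for ribosome biogenesis, 0.08 for aminoacyl-tRNA synthetases, -0.07 for ribosomal proteins and -0.20 for the respiratory chain. None of these calls held with an estimated correlation (adjusted p from 0.0615 to 0.643), and 0 of 54 ribosomal protein genes passed.

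The genes with a higher polysomal effect had a median of -0.68 for polysomal against cytoplasmic RNA in control cells and -0.02 in 4EGI-1 cells. They were selected on a difference that holds the control value with its sign turned, so these medians alone do not show depletion in control cells. With no effect at all the 2 correlated at -0.71 in simulations (-0.65 observed), with a covariance of -0.0127 against an observed -0.0478. The spread of shared arrays thus gives part of the relation across genes and not all of it. Variation among the cytoplasmic arrays is argued against as the cause, since the median cytoplasmic effect of these genes was -0.01 (quartiles -0.14 and 0.10). A candidate explanation is a recovery of long RNAs in the pooled polysome fractions that differed between control and 4EGI-1 samples: 114 genes of large proteins had a median difference of effects above that of 88 genes of small proteins by 0.42 (95% bootstrap interval 0.33 to 0.50). The interval comes from resampling the genes of the lists, so it holds no variation between arrays or cultures. In control polysomes the large-protein genes had a median of -0.26 and the small-protein genes 0.20, and in 4EGI-1 polysomes the medians were -0.02 and 0.04. A response of translation to 4EGI-1 that depends on length, open as a biological hypothesis, predicts the same values, and transcript lengths were not analysed here.

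Of the large-protein genes 66 rose and 3 fell in polysomal RNA, and of the small-protein genes 0 rose and 49 fell, with medians of 0.34 and -0.34. In cytoplasmic RNA 19 large-protein genes rose and 5 fell (median 0.08), and 0 small-protein genes rose and 10 fell (median -0.13). Camera gave p = 0.000934 and p = 7.07e-05 there, and p = 0.338 and p = 0.215 with an estimated correlation. Recovery from polysome fractions does not predict this cytoplasmic part, which is subtracted in the difference of effects. In the difference of effects 20 large-protein genes passed, all higher, and 0 small-protein genes. Camera with an estimated correlation gave p = 0.0282 for the large-protein list and p = 0.0826 for the small-protein list.

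For the difference of effects, the arrays were regrouped within each fraction with additive effects removed. A first set of groupings, drawn across fractions, gave a share under 0.05 and was set aside, because removing additive effects fixes the outcome of some of them. Within fractions 8 of 100 groupings called as many genes as the real 385, the real one included, so chance cannot be excluded by this test. The highest of the others called 2287. That grouping kept the polysomal groups and put cytoplasmic control arrays 1 and 3 together with cytoplasmic 4EGI-1 array 3. Every other grouping that called as many genes parted the cytoplasmic arrays in this way, which points to a structure of the cytoplasmic samples. Some groupings that parted them so called 0 genes, so the count also depended on how the polysomal arrays were grouped.

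Probe sets without a gene name, 5823 of which were tested, also responded to 4EGI-1. In cytoplasmic RNA 270 were higher and 130 lower, and in polysomal RNA 503 were higher and 321 lower.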

How the results depend on the processing

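Settings added after the data were seen were the first within-group component as a covariate, and leaving out cytoplasmic control 2 with cytoplasmic 4EGI-1 3. The results compared were 160 of genes, 32 of lists and 10 counts, and each was counted once per setting. Outside the fits without single arrays, 2171 such gene comparisons were the same, 34 lost and 16 gained their call, and 5 changed sign. Of list comparisons, those with fry included, 436 were the same and 44 did not pass. Of counts 114 stayed within 1.5 times and 26 did not. Without single arrays, these numbers were 1857, 48, 3 and 12 for genes, 375 and 9 for lists and 95 and 25 for counts. The cause was not tested unless the setting names it. No scaling moved the median of all genes by over 0.1. Signal over background limits the dim genes.

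A minimum of 1.5-fold, stricter by construction, left 420 genes higher and 174 lower in cytoplasmic RNA, 604 and 279 in polysomal RNA, 34 lower in the difference of effects, and for polysomal against cytoplasmic RNA 559 and 448 in control and 149 and 196 in 4EGI-1 cells. Genes lower in the difference of effects were 28 without a filter and 125 with arrays of the same treatment and number as a random block (consensus correlation 0.09). With every probe set as its own feature, 2715 were lower in polysomal RNA of control and 1773 of 4EGI-1 cells. Fits of only the groups compared gave 731 higher and 369 lower in cytoplasmic and 2685 lower in polysomal RNA. With the component as a covariate, 2071 were lower in cytoplasmic and 2464 in polysomal RNA, 615 higher and 397 lower in the difference, 2446 lower in polysomal RNA of control cells, and 2058 higher and 1774 lower in that of 4EGI-1 cells. That covariate was taken from the deviations of the same fit. It takes out spread and leaves the fold changes unmoved, so higher counts are built in. Without cytoplasmic control 2 and cytoplasmic 4EGI-1 3, 2512 were lower in cytoplasmic RNA, and 1081 were higher and 852 lower in the difference. The cytoplasmic arrays left differ between treatments along the component, so these counts may hold it.

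Without single arrays, counts ranged in cytoplasmic RNA from 869 to 1505 higher and 588 to 1622 lower, in the difference from 179 to 411 higher and 19 to 259 lower, and in polysomal against cytoplasmic RNA of 4EGI-1 cells from 549 to 1505 higher and 497 to 1143 lower. Values that changed sign were not called. In cytoplasmic RNA, Myc ranged from -0.282 to 0.032, Mcl1 from -0.311 to 0.02 and Odc1 from -0.031 to 0.106, and in the difference Mcl1 ranged from -0.218 to 0.112 and Ddit3 from -0.079 to 0.082. Cytoplasmic Eif4e was 0.132 with the mean of its probe sets. Without the pair of cytoplasmic arrays, cytoplasmic Odc1 was -0.064 and Eif4e 0.001, and the differences of Mcl1 and Ddit3 were 0.147 and 0.124. There Myc (-0.40; limma, adjusted p = 0.00712) and Notch1 (-0.533; 0.000606) were called lower in cytoplasmic RNA. Notch1 was called higher in polysomal RNA (0.317; 0.00462), and the differences of Myc (0.619; 0.00608) and Notch1 (0.85; 0.000451) passed. The cytoplasmic arrays left had component scores of 0.06 and 0.48 in control and -0.17 and -0.38 in 4EGI-1. The component and the treatment can therefore not be told apart in the cytoplasmic values and differences of this setting. List calls lost there were cytoplasmic respiratory chain (0.18) and small nucleolar RNAs (0.427), and ribosomal proteins in the difference (0.297). With the component as a covariate the differences of Myc (limma, adjusted p = 0.0272), Notch1 (0.0251) and Odc1 (0.0316) passed at unmoved fold changes, in a setting that gains calls by construction.

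List calls lost in cytoplasmic RNA were those of the respiratory chain (adjusted p = 0.0519 after quantile normalization of all arrays) and T cell identity (0.0703 after that normalization, 0.0706 within fractions). Polysomal G2/M and mitosis had 0.0549 and 0.0591 after these normalizations. At the 60th percentile filter, which tests fewer genes, cytoplasmic small nucleolar RNAs had 0.299 and T cell identity 0.0544, and polysomal small nucleolar RNAs had 0.126, eIF4E-sensitive mRNAs 0.057, ribosome biogenesis 0.0532 and G2/M and mitosis 0.0918. Fry does not compare a list with other genes and so does not test the camera calls. It gave an adjusted p of 0.0602 for the cytoplasmic respiratory chain and, in the difference, 0.107 for ribosomal proteins and 0.0803 for G1/S. The other lists that camera called in cytoplasmic RNA, polysomal RNA or the difference passed fry (adjusted p from 1.65e-06 to 0.0478). So did some that camera did not call, such as eIF4F and its regulators (fry, adjusted p = 0.0124 in cytoplasmic and 0.00168 in polysomal RNA).

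With the replicate block, 1462 genes were higher and 1312 lower in cytoplasmic RNA, 1833 and 1812 in polysomal RNA, and 352 and 120 in the difference. In polysomal against cytoplasmic RNA they were 2346 and 1842 in control and 1442 and 1140 in 4EGI-1 cells. Of 18 same-numbered pairs, 9 had deviations correlated over 0.1 (-0.22 to 0.56), 12 correlated best with their own number, and all those numbered 2 were over 0.1 (0.14 to 0.56). Pairing required every pair over 0.1, so the main fit used no pairs (the naming rule for the difference subtracts arrays of the same number), and a factor shared by arrays of a number, most of all number 2, stays open. When polysomal minus cytoplasmic values between arrays of the same number were fitted, 278 genes were higher and 79 lower in the difference. Of these, 256 and 56 were also called in the main fit, which called 305 and 80.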

Other observations

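The genes and gene groups described here were chosen after their values were seen. The test of a step shared by arrays of the same number was written after its result was seen.

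Zinc finger protein genes were more often among the genes that rose than other genes were, though most did not pass. Of 271 tested genes with Zfp symbols, 104 rose and 7 fell in cytoplasmic RNA (38.4% higher against 9.46% of other genes; Fisher's exact test, two-sided, odds ratio 5.96, p = 3.99e-36). In polysomal RNA 115 rose and 7 fell (42.4% against 12.4%, Fisher's exact test, odds ratio 5.2, p = 6.58e-34), with medians of 0.19 and 0.22, and 87 rose in both. Camera with an estimated correlation gave p = 0.00721 and p = 0.0102. Their presence in the polysomal arrays at a median of 0.22 argues against the component that varies among the cytoplasmic arrays. Examples are Zfp605 (1.29 ± 0.14 and 1.13 ± 0.14, SE) and Zfp759 (0.98 ± 0.12 and 1.48 ± 0.12). Many Zfp genes are near copies of one another, and probe sets can share their signal. Fisher's test counts genes on the same arrays as independent, and the group was chosen for its values, so these p-values overstate the evidence.

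Single genes beyond those named by the rule were these. The zinc exporter gene Slc30a1 rose by 1.06 ± 0.12 in cytoplasmic and 0.94 ± 0.12 in polysomal RNA, beside the metallothionein gene Mt2 (1.99 ± 0.17 and 1.71 ± 0.17), while Mt1 had 0.08 ± 0.11 and 0.16 ± 0.11 and did not pass. The splicing kinase genes Clk1 (0.76 ± 0.15 and 0.69 ± 0.15) and Clk4 (0.83 ± 0.11 and 0.59 ± 0.11) rose. Of NOTCH targets, Hes1 rose (0.73 ± 0.15 and 0.98 ± 0.15) and Nrarp fell (-0.76 ± 0.11 and -0.83 ± 0.11), while the NOTCH target list did not pass camera (adjusted p = 0.267 and 0.739). The snoRNA host genes Snhg5 (1.31 ± 0.10 and 1.23 ± 0.10) and Snhg17 (0.56 ± 0.11 and 0.65 ± 0.11) rose, while Gas5 (0.20 ± 0.09 in both fractions) and Snhg15 (-0.09 ± 0.11 and -0.19 ± 0.11) did not pass. These are the 4 tested members of a list of such genes that leaves out Snhg16, so 2 of 4 rose in each fraction. Eif4g3, a relative of the eIF4G scaffold, rose in polysomal RNA (0.62 ± 0.10) at a cytoplasmic change of 0.00 ± 0.10, with a difference of effects of 0.62 ± 0.15 (limma, adjusted p = 0.033).

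The cytoplasmic arrays differed within their groups along 1 component, with scores of -0.53 and -0.38 in control 2 and 4EGI-1 2, and 0.48 and 0.54 in control 3 and 4EGI-1 3. Wrong labels on these arrays are argued against: on an axis of 883 genes that changed in polysomal RNA, with the other control arrays at 0 and the other 4EGI-1 arrays at 1, control 2 lay at 0.01 and 4EGI-1 3 at 0.97. A processing step shared by arrays of the same number stays open: deviations of control and 4EGI-1 arrays correlated at 0.56 for number 2 and 0.52 for number 3, and at -0.22 for number 1. Of the 10 splits of the 6 cytoplasmic arrays, 1 called as many genes as the real 2352, that split itself, and the highest other, control 1, control 3 and 4EGI-1 3 against the rest, called 2011. The splits are too few for a share under 0.05, and no biological explanation was tested.

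In the other comparisons, too, 1 of 10 splits called as many genes as the real one, that split itself, and 10 splits are too few for a share under 0.05. The real and highest other counts were 3316 and 0 in polysomal RNA, and 3819 and 0 in control and 2202 and 0 in 4EGI-1 cells for polysomal against cytoplasmic RNA.

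Among 4394 dim genes (mean control value up to 7.0), 27 rose at least 2-fold in both fractions, such as Wap (1.57 ± 0.12 and 1.51 ± 0.12), a milk protein gene, and Mttp (1.09 ± 0.11 and 1.31 ± 0.11), a lipid transfer gene. An upward drift of all dim probe sets is argued against by their median effects of -0.01 and -0.02. A candidate explanation is transcription running on from an expressed neighbour: 14 of 27 (51.9%) had a gene of log2 value 9 or more within 10 kb, against 912 of 4342 other dim genes (21%), a ratio of 2.47 (95% interval 1.71 to 3.57; Fisher's exact test, two-sided, p = 0.000413). Strand was not tested, and activation of these genes by 4EGI-1 stays open.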
